A study of Arabidopsis thaliana with 14 samples.

How the data were processed

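The series holds 14 samples of Arabidopsis thaliana seedlings in 7 groups of 2: m6A sequencing of the wild type Col0 (14-day seedlings), poly(A) site sequencing of Col0 and of the cpsf70 mutant, CLIP of a line that overexpresses FLAG-tagged CPSF70 and of Col0, and RNA-seq of Col0 and cpsf70 (12-day seedlings). Groups and replicate numbers came from the sample titles. No label says that replicates came from separate plantings, so the p-values measure the spread between these samples, which may be technical. The 2 CLIP samples of Col0 have no table of their own and were not analysed here.

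Per the labels' protocols, all libraries started from poly(A) RNA. Poly(A) sites were mapped by A-seq2, in which reverse transcription starts at the poly(A) tail; m6A was enriched from fragmented RNA with an antibody; and CLIP used formaldehyde crosslinking, RNase T1 and an anti-FLAG pull-down. The submitters' processing notes name cutadapt 1.18, HISAT2 2.1.0, MACS2 2.2.5 and the TAIR10 genome, and their order and settings are not given in the sources used here. All coordinates are TAIR10 positions as the authors gave them.

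The authors deposited 1 table of poly(A) clusters per poly(A) library, with the level of each cluster in TPM, per the file headers. The tables hold fractional reads. The value of a single read was recovered from the spacing of the low values: 0.159 and 0.308 TPM in Col0 replicates 1 and 2, and 0.257 and 0.164 TPM in cpsf70 replicates 1 and 2. The depth implied is 6.27, 3.25, 3.88 and 6.09 times 1e6 reads. Only 85.3%, 72.2%, 79.1% and 71.1% of the values lay within 0.01 read of a whole multiple, so a test on whole reads was not run. The Col0 tables list nuclear clusters of at least 3 TPM and at most 51 nt. Both cpsf70 tables list the same 29896 clusters of up to 147 nt, of which 5944 lie below 3 TPM in replicate 1. Cluster bounds were drawn separately for each genotype, and presence in both cpsf70 tables is therefore a single event. Both cpsf70 tables also carry the same internal name. Their values differ throughout (0 identical values), so they were used as 2 libraries, but the names leave open whether these are distinct replicates. The authors deposited m6A and CLIP peaks per replicate, without strand, with a −log10 p-value and a fold enrichment per the file headers. Peak folds in the text are the authors' values. The internal names of the CLIP tables give the replicate numbers the other way round. The sample titles were followed, and what the peaks were called against is not given in the sources used here. The RNA-seq table of the whole series gives FPKM per library, a fold and a p-value for 168 genes, as deposited by the authors, and was preselected (the scale of the fold is not stated, and it lies near the ratio of mean FPKM + 1): no p-value in it exceeds 0.0497.

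Clusters of the 4 poly(A) tables were joined on each strand where at most 24 nt lay between them, and TPM was summed per library. This gave 30191 sites, of which 13668 were listed in all 4 tables. The joining rule has a history that matters for the results. Joining by gaps was looked at first without testing, then clusters were joined around midpoints within 24 nt and tested, and joining by gaps was taken up again after the calls with midpoints had been seen. Both counts are given in the results.

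Gene names and spans came from RefSeq genes of assembly TAIR10.1, which gave no strand here. The strand of each gene was inferred from the poly(A) tags in the 40% of the span at each end and 200 nt beyond it, or from inner tags where at least 90% shared a strand. This rule was set while looking at the data. It gave a strand to 15427 genes, 14347 by their ends and 1080 by inner tags. Of the sites, 86.3% fell in a gene, against 23.5% after all positions had been moved by 50000 nt. Exons, introns and UTRs were not used here, and no genome sequence was used, so sequence motifs were not analysed here.

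Differences between genotypes were tested with limma 3.58.1 (R 4.3.3), with eBayes and 2-sided p-values adjusted after Benjamini-Hochberg at a threshold of 0.05, on log2(TPM + 1) with no block. A change on this scale understates the change of low values. Sites were tested where listed in all 4 tables. Gene totals summed these sites only, so a site missing from any table was left out of the total of its gene. Site use was log2((distal + 1) / (proximal + 1)) of the 2 most abundant sites of a gene, with distal and proximal ordered along the gene. In the main fits of site abundance and gene totals limma found no spread that differed between features (infinite prior degrees of freedom). A single standard error therefore applies to all, and a feature extreme in 1 library can pass. After rescaling by median ratios the prior degrees of freedom were 2.17 and 2.39, so spreads then differed between features. The single standard error depends on the scaling and is no fixed property of the features. For the RNA-seq table, limma on log2(FPKM + 1) was run over the listed genes only. With 2 libraries against 2, values of unchanged features do not overlap between genotypes in 33.3% of cases. Overlaps of genes and of windows were tested with 2-sided Fisher's exact tests, peak overlaps against 100 shuffles of the peaks, and windows upstream of sites against 20 random placements within the same gene. Intervals are at 95%, Wilson for shares and bootstrap (2000 draws) for differences of medians, and cover counting error only. Gene lists were tested with camera, with its preset and with an estimated correlation.

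The tests, the samples in each, the alternatives that are called planned in the closing part, 10 gene lists and the rule for named genes were fixed before the data were examined. The lists cover the polyadenylation machinery, m6A writers, erasers and readers, flowering time, nitrate signalling, abscisic acid, defence, oxidative stress, photosynthesis, root markers and genes discussed for this reader. By the rule, the text names the 10 largest changes of site use each way among genes past the threshold whose genotypes do not overlap, and the 5 with the smallest p where fewer than 10 passed in a direction. It names the 5 largest changes of site abundance each way, the 5 most abundant sites listed in a single genotype, the 10 largest folds each way of the RNA-seq table and the 5 genes with the highest peak fold in both replicates. CPSF30, SOC1, RPN10 and FYVE1 are always named, as are list members past the threshold or otherwise the 2 with the largest change. Publications on this reader name the last 3 genes, which are therefore no independent evidence. A list of 25 phosphate starvation genes was chosen after the RNA-seq table had been seen.

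Alternatives were another pseudocount (0.5), a minimum mean of 10 TPM, a replicate block, leaving out each library, other joining rules, a variance trend, absent values set to 0, rescaling by median ratios, other peak thresholds, overlaps and windows. An alternative added after the calls had been seen kept only joined sites whose strongest cluster in each table overlapped a cluster of every other table.

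The limma step was tested on simulated data made from the real means with 200 changed features. One version gave all features the same spread, as limma found for site abundance and gene totals without rescaling. There 15 of 67 changes of log2 1, 65 of 67 of log2 2 and 66 of 66 of log2 3 were recovered among 13668 sites, with 9 false calls. For 10126 gene totals the counts were 23, 65 and 66, with 6 false calls, and for site use in 2001 genes 20, 65 and 66, with 5 false calls. A first version gave each feature its own spread. It recovered none of the changed sites, 0, 28 and 46 gene totals and 2, 24 and 43 genes for site use. For site use the prior degrees of freedom were 3.84 in the real fit, 49.8 with one spread and 1.54 with own spreads. The counts with one spread are therefore too favourable for site use. For sites and gene totals own spreads gave 1.98 and 2.26, near the 2.17 and 2.39 of the real fits after rescaling. The overlap step found 6000 of 6000 simulated overlaps, and the joining step 10000 of 10000 sites. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.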

Results

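Poly(A) site use, m6A, CPSF70 binding and transcript levels were measured in Arabidopsis seedlings to ask how CPSF70, a subunit of the cleavage and polyadenylation machinery that carries an m6A-binding domain, affects the choice of poly(A) site. The cpsf70 mutant was compared with wild-type Col0 in 2 poly(A) libraries per genotype, where a single read equals 0.159 and 0.308 TPM in Col0 and 0.257 and 0.164 TPM in cpsf70. The libraries of a genotype correlated across sites with r = 0.905 in Col0 and 0.908 in cpsf70, and libraries of different genotypes with 0.841 to 0.892. No pair of libraries was a duplicate (chi-square per degree of freedom of at least 24.4). By this chi-square the 2 Col0 libraries were the least alike pair (43.9). They differed more from each other than from the cpsf70 libraries (24.6 to 41.2).

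The mutated locus, CPSF30 (AT1G30460), which also encodes the longer CPSF70 protein, was lower in cpsf70 seedlings. In the authors' deposited table it stood at 5.58 and 4.87 FPKM in Col0 and at 0.542 and 0.593 FPKM in cpsf70, a ratio of mean FPKM of 0.109, while the fold listed there is 0.247. Its poly(A) clusters were not analysed here.

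The transcript table asks which genes differ in level between the genotypes. The authors' deposited table lists 168 genes, of which 99 were higher and 69 lower in cpsf70, all preselected by fold and p-value. For 2 of these genes, AT1G12310 and AT5G09620, the listed fold goes against the means of the FPKM listed in the authors' deposited table. The folds of the authors' deposited table lie within 5% of the ratio of mean FPKM + 1 for 156 of 168 genes and of the plain ratio for 59, so they understate changes of genes with low FPKM, and the order below follows the listed folds. Among the largest rises in the authors' deposited table were ADT6, an arogenate dehydratase of phenylalanine synthesis, at 0 FPKM in both Col0 libraries and 12.1 and 11.8 FPKM in cpsf70, emb1513 (fold 12.5), the microRNA gene MIR163 (fold 8.13, plain ratio 124) and RRA3 (fold 3.60). The authors' deposited table also lists ENSRNA049495736, AT1G07940, AT2G11910, AT3G03975, SLD2 and AT4G12500 among the 10 largest rises, with folds from 2.84 for AT4G12500 to 6.19 for ENSRNA049495736. The largest falls in the authors' deposited table were ENSRNA049757750 (fold 0.103, plain ratio 0.00766), AT2G09700 (fold 0.172, plain ratio 0.0475) and BGL2, the pathogenesis-related glucanase PR2 (fold 0.199, plain ratio 0.131), followed by CPSF30. ECI1, ENSRNA049495703, ACO1, PTR6, AT4G22495 and AIG1 completed the 10 largest falls, with folds from 0.291 for ECI1 to 0.391 for AIG1 in the authors' deposited table.

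Of the fixed lists, defence had 3 members in the authors' deposited table, all lower (PR2, WRKY70 and VSP2), and abscisic acid 2, both lower (COR15A and RAB18). Photosynthesis had 3 members in the authors' deposited table, all higher: the light-harvesting genes LHCB1.1, LHCB1.2 and LHCB2.1. The authors' deposited table further lists the floral repressor FLC as lower (fold 0.655) and the phosphate transporter PHT1;4, a root marker, as higher (fold 1.75). The lists of m6A writers, erasers and readers, nitrate signalling, oxidative stress and genes discussed for this reader had no member in it. limma over the 168 genes, with Benjamini-Hochberg adjustment, called 163 (97 higher, 66 lower), which is no independent test of genes selected on the same values.

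**Figure D1:**
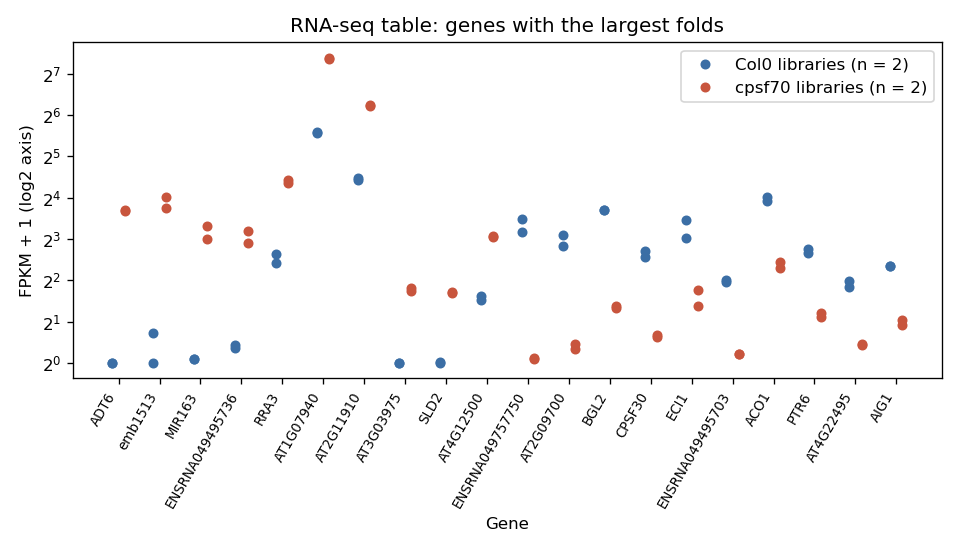
FPKM + 1 on a log2 axis for the 20 genes with the largest folds in the authors' deposited table, with 1 point per library (Col0 and cpsf70, n = 2 each). CPSF30 stands at 5.58 and 4.87 FPKM in Col0 and at 0.542 and 0.593 FPKM in cpsf70.

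Gene totals of the poly(A) tags give the level of the same transcripts in separate libraries. Of the genes in the authors' deposited table, 73 had a poly(A) total, and 51 of them (69.9%, interval 58.0 to 80.1) had the same direction there (exact binomial test, 2-sided p = 0.000914), with a correlation of log2 values across genes, which are not independent, of r = 0.156. Of these, 2 passed in the poly(A) totals: the cell wall kinase WAK1, which fell by 1.67 on the log2 scale, and GDPD2, a phosphodiesterase, at 1.56. GDPD2 rests on 1 library, with 37.3 and 41.2 TPM in Col0 and 872 and 15.1 TPM in cpsf70. COR15A, lower in the authors' deposited table (fold 0.580), had a poly(A) change of 1.19 that did not pass. The largest rises of that table were not repeated in size. ADT6 had 0.10, AT2G11910 0.39, emb1513 −0.58, AT1G07940 −0.28 and AT4G12500 −0.26. Of its largest falls, PTR6 had −0.18 and ACO1 0.42. None of these passed, and the other named rises and falls had no poly(A) total. Over all 10126 genes, limma with Benjamini-Hochberg adjustment called 22 higher and 154 lower in cpsf70. With absent values set to 0, which brings in the missing sites, it called 1670 genes, and 75 of them were also called here. Genotypes did not overlap in 35.9% of all genes, against 33.3% by chance.

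ABI2, a phosphatase that restrains abscisic acid signalling, and the defence marker PR1 were the members of fixed lists whose totals fell. ABI2 fell by 2.39 (SE 0.44; limma, Benjamini-Hochberg adjusted p = 1e-05), from 5.53 and 26.2 TPM to 0.601 and 3.02 TPM. It had −1.36 without Col0 replicate 2 and −1.73 without cpsf70 replicate 1, and passed in neither case nor after rescaling by median ratios. PR1 fell by 1.47 (SE 0.44; limma, Benjamini-Hochberg adjusted p = 0.0475), from 15.9 and 11.1 TPM to 3.60 and 4.76 TPM, and did not pass with any of the 4 libraries left out. Adjusted over the list alone the same 1 member passed in each of these lists, and in the polyadenylation machinery 1 more, CLPS3 at −1.43, with 0 TPM in cpsf70 replicate 1. The polyadenylation gene SYM2 (−0.89), the m6A writers MTA (0.72) and FIP37 (−0.53), the flowering genes SVP (0.60) and SOC1 (−0.54), the nitrate genes NLP7 (0.60) and NIA2 (0.53), the antioxidant genes CAT3 (0.49) and TRX5 (0.47) and the photosynthesis genes LHCB1.3 (1.11) and PSAD1 (0.52) did not pass. Neither did RPN10 (−0.16), FYVE1 (0.24), PHT1;1 (0.19) or PHT1;4 (−0.12). No list passed camera: the smallest preset p of a fixed list was 0.192, for photosynthesis, and its p with an estimated correlation was 0.791.

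Rescaled by median ratios, limma called 3 higher and 43 lower, and with sites limited to overlapping strongest clusters 21 higher and 80 lower. PR1 passed in neither. Without cpsf70 replicate 1 it called 114, and with clusters joined around midpoints 95 higher and 79 lower.

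The site comparison asks whether transcripts end at other poly(A) sites in the mutant. Across 2001 genes with 2 measured sites, the distal site made up a smaller part in cpsf70: the median of log2(distal / proximal) was 1.32 and 1.27 in the Col0 libraries and 1.13 and 0.83 in the cpsf70 libraries. The change was toward the proximal site in 1430 genes (71.5%), with a median of −0.40. It lay at −0.22, −0.36 and −0.61 in the terciles of genes from the least to the most abundant. In 1474 genes whose less abundant site was proximal the median was −0.48 (77.3% negative). In 527 genes whose less abundant site was distal it was −0.10 (55.0% negative). The tendency therefore lay mostly in genes whose proximal site is the weaker one. Genotypes did not overlap in 56.2% of all genes tested for site use, against 33.3% by chance. The genotypes differed by 0.313 in the mean of their library medians, while the 2 cpsf70 libraries differed from each other by 0.302. Genes of a library are not independent, so these counts of genes do not measure the spread between libraries.

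Photosynthesis genes lay on the proximal side throughout: 22 of 22 measured members had a negative change, with a median of −0.82. In the most abundant tercile of all genes 81.9% were negative, with the median of −0.61. LHCB3 (−1.38), LHCB2.1 (−1.26), encoding light-harvesting proteins, and FBA2 (−0.93), an aldolase of the Calvin cycle, had an unadjusted p under 0.05 in limma, and no member passed over all genes or adjusted over the list alone. In the other lists 4 of 5 nitrate genes, 4 of 5 antioxidant genes, both m6A readers measured (ECT2 and ECT3) and the only polyadenylation gene measured (PAPS2) had negative values, and 0 of 4 abscisic acid genes did. None of these passed limma over all genes. The flowering regulator MAF2, at −1.18, passed only when adjusted over the list alone, as the only member measured.

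limma with Benjamini-Hochberg adjustment called 11 genes toward the proximal site and 0 toward the distal one. At an unadjusted p under 0.05 there were 298 and 74, and limma's diffSplice called 72 genes. HOG1 (AT4G13940), the S-adenosylhomocysteine hydrolase that recycles the by-product of methylation, had the largest change, −5.83 (SE 0.43; limma, Benjamini-Hochberg adjusted p = 0.0218). Its distal site (chromosome 4, 8056925 to 8057074) went from 411 ± 43.5 to 18.4 ± 5.33 TPM, and its proximal site (8056171 to 8056898) from 49.7 ± 19.8 to 128 ± 8.81 TPM (SD, n = 2). The proximal site is 728 nt wide, and with clusters joined within 50 nt HOG1 had −2.96 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0922). PKP-BETA1, a subunit of plastid pyruvate kinase, had −4.16 (SE 0.34), with a distal site (chromosome 5, 21466774 to 21466866) at 60.5 ± 7.69 TPM in Col0 and 3.19 ± 0.0178 TPM in cpsf70 (SD, n = 2). The plastid ribosomal gene PRPL28 (−4.83), AT3G04840 (−4.37), the glutathione peroxidase GPX2 (−3.77), the pectin methylesterase PMEPCRA (−3.66), AT2G04900 (−3.59), AT3G56310 (−3.56), the MYB factor MYBR1 (−3.50) and AT5G62350 (−3.23) followed, with emb1138 (−2.96) as the last. Toward the distal site, AT5G66050 (4.19), emb2726 (2.26), APK (2.22), MYC2 (2.18) and MBF1B (2.04) came closest without passing (limma, Benjamini-Hochberg adjusted p from 0.0739 to 0.0817).

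**Figure D2:**
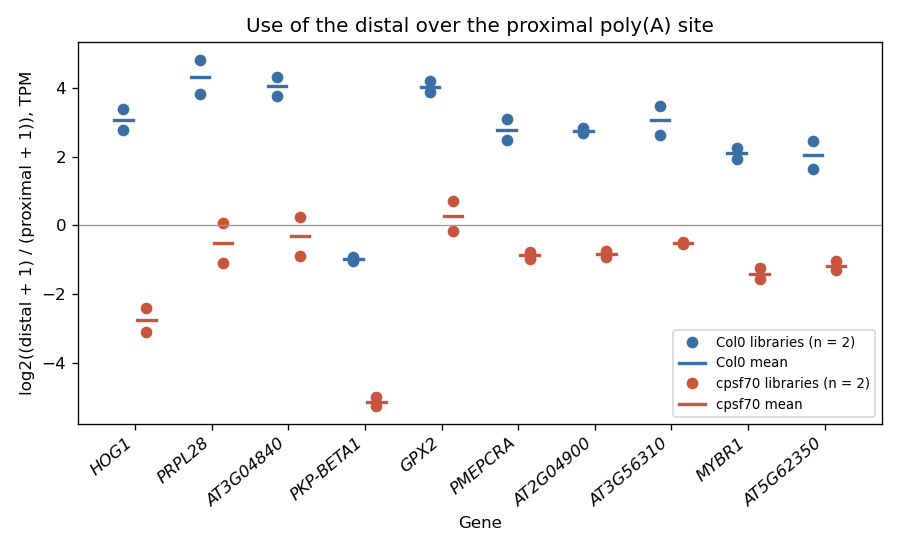
log2 ratio of the distal to the proximal poly(A) site (TPM + 1) in the 10 genes with the largest called change, with 1 point per library and a line at the mean (n = 2 per genotype). In HOG1 the Col0 libraries stand at 2.77 and 3.38 and the cpsf70 libraries at −2.41 and −3.11; in all 10 genes a strongest cluster has no overlapping counterpart between the tables.

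In all 11 called genes a strongest cluster of the pair of sites had no overlapping cluster in another table, against 167 of 1990 uncalled genes (8.39%). A cluster listed in a single genotype makes a large change and a missing overlap together, so leaving out such sites removes the pairs of sites of these genes by construction. Without them limma called 0 of 1853 genes (309 at an unadjusted p under 0.05). HOG1, then measured on another pair of sites, had a change of −0.05. The median over all genes was −0.38 with 71.5% negative. The authors' deposited table lists HOG1 as higher in cpsf70 (fold 1.83), while its poly(A) total had −1.15, which did not pass. Clusters joined around midpoints gave 188 distal and 362 proximal calls among 3313 genes, with HOG1 at 0.40, PRPL28 at −1.01, AT5G62350 at −0.24, APK at −0.10 and emb2726 at −0.038, and a median of −0.25. With midpoints PMEPCRA (−1.28), GPX2 (−1.98) and emb1138 (−1.67) still passed at smaller changes, and AT5G66050 (4.19), MYC2 (2.02) and MBF1B (2.01) passed toward the distal site. The calls numbered 5 without Col0 replicate 1 (3 distal, 2 proximal), 0 without Col0 replicate 2 (203 at an unadjusted p under 0.05), 42 without cpsf70 replicate 1 (5 distal, 37 proximal) and 26 (6 distal, 20 proximal) without cpsf70 replicate 2, and the median was −0.23 without cpsf70 replicate 2. The photosynthesis median was −0.54 without Col0 replicate 2, −1.26 without cpsf70 replicate 1, −0.44 without cpsf70 replicate 2 (20 of 22 negative) and −0.39 with midpoints (18 of 26 negative).

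**Figure D3:**
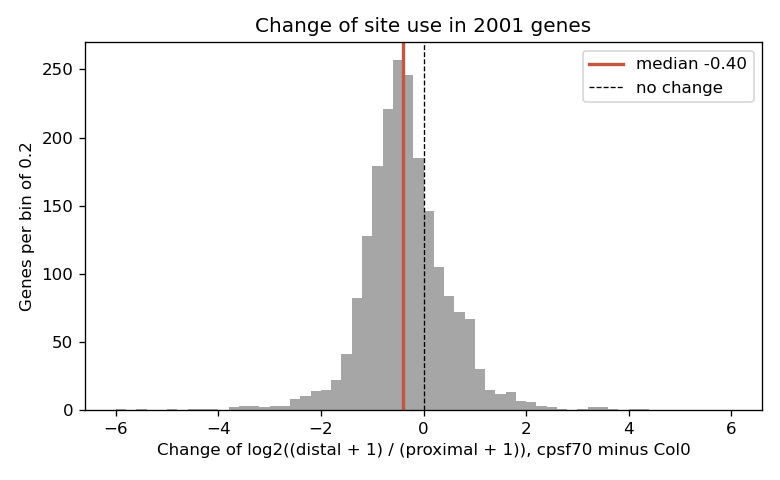
Number of genes by change of log2((distal + 1) / (proximal + 1)), cpsf70 minus Col0, for 2001 genes in bins of 0.2. The solid line marks the median of −0.40 and the dashed line no change.

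Single sites were compared to see which cleavage positions gain or lose tags. limma with Benjamini-Hochberg adjustment called 84 sites higher and 217 lower in cpsf70 among 13668 (SE 0.49 for every site). Genotypes did not overlap in 40.3% of all sites, against 33.3% by chance. The direction turned with clusters joined around midpoints (274 higher, 185 lower) and with absent values set to 0 (3106 higher, 2432 lower), and robust eBayes called 275 higher and 297 lower. The largest fall was at AT4G00695 (chromosome 4, 284377 to 284406), at −9.75, from 2249 and 3287 TPM in Col0 to 1.44 and 3.08 TPM in cpsf70. A site outside genes on the same chromosome (294420 to 294433) fell by 7.34, and AOX2, an alternative oxidase (chromosome 5, 25685213 to 25685232), fell by 5.13, from 149 and 225 TPM to 0 and 26.9 TPM, with −2.72 without cpsf70 replicate 1. The largest rise was at a site outside genes (chromosome 2, 10760955 to 10760973), by 6.51, from 4.53 and 9.07 TPM to 798 and 574 TPM, followed by AT3G25510 (chromosome 3, 9265256 to 9265284) at 5.07.

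The other 5 named sites were extreme in 1 library. AT5G56220 (chromosome 5, 22755220 to 22755239; −5.16) and AT3G14600 (chromosome 3, 4911084 to 4911103; −4.95) were high in Col0 replicate 1 alone and had −0.90 and −0.78 without it. Chromosome 4, 4899908 to 4899926 (3.94), AT5G28696 (chromosome 5, 10739224 to 10739245; 3.60) and the response regulator RR1 (chromosome 3, 5756126 to 5756147; 3.40) were high in cpsf70 replicate 2 alone and had 1.58, 1.15 and −0.94 without it. Rescaled by median ratios, limma called 1 site higher and 33 lower, and over sites with overlapping strongest clusters 51 and 119. Without Col0 replicate 2 it called 179 sites and without cpsf70 replicate 1 189.

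Sites listed in a single genotype were counted without a test, since an absent site is below the floor of a table or absent for another reason. Both Col0 tables alone listed 2318 sites, at a median of 140 nt upstream of the gene end, close to the 136 nt of sites in all 4 tables. Both cpsf70 tables alone listed 4425 sites, at a median of 748.5 nt upstream. The most abundant in Col0 lay in AT2G36670 (chromosome 2, 15367726 to 15367752) at 17847 and 20733 TPM and in AT2G06770 at 2464 and 3244 TPM, while those in PEX3-1, AT5G66840 and AT1G08280 were high in 1 library. In cpsf70, AT3G14870 had 312 and 293 TPM, and the other 4 (chromosome 3, 15727504 to 15727526, AT4G17260, AT1G73920 and WAV2) were high in replicate 2 only. The direction of the counts turned at a mean of 10 TPM (368 in Col0, 167 in cpsf70) and with cpsf70 replicate 1 held to the 3 TPM floor of the others (1738 in cpsf70).

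m6A and CPSF70 binding were then placed on transcripts. The wild-type m6A libraries gave 12620 and 12352 nuclear peaks with a median length of 357 and 355 nt, and 90.4% and 91.6% overlapped a peak of the other replicate, against 16.2% of peaks shuffled over expressed genes and 44.2% within the same gene. CLIP of FLAG-CPSF70 gave 14606 and 12427 peaks of 52 and 53 nt, and 43.9% and 51.6% were shared, against 3.45% and 15% of shuffled peaks. Shuffles within the same gene left peaks outside expressed genes in place. Of the replicate 2 peaks, 68.4% (m6A) and 74.1% (CLIP) lay in an expressed gene and were moved. The 44.2% and 15% therefore include overlaps of peaks that were not moved. The highest m6A folds in both replicates were at AT1G64572 and its neighbour AT1G64580, which share a peak (17.0 and 18.3), the glucosidase gene GCS1 (16.8 and 23.8), and UGT74F1 and AT2G43850, which share a peak (16.2 and 22.4). What the CLIP peaks were called against is not given in the sources used here. The highest CLIP folds were at CPSF30 itself, the gene overexpressed in that line (19.4 and 21.9), AT1G08875 (16.7 and 18.5), AT3G05730 (15.3 and 15.1), and chx28 and the RNA polymerase II subunit gene NRPB11, which share a peak (16.2 and 15).

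Bound transcripts carried m6A more often than others. Among 11378 genes with poly(A) clusters in both Col0 tables, 4010 had both kinds of peak, and 83.5% of CLIP genes had m6A against 65.1% of the rest (odds ratio 2.72, interval 2.48 to 2.98). The odds ratio was 2.64, 2.72 and 2.97 in the bottom, middle and top terciles of poly(A) level. Of 6414 CLIP peaks found in both replicates, 3183 (49.6%, interval 48.4 to 50.8) overlapped an m6A peak, against 12.7% after shuffling over expressed genes and 20.3% within the same gene (permutation p = 0.01, the smallest that 100 shuffles can give). Within the same gene only the 78.1% of CLIP peaks in an expressed gene were moved, so the 20.3% includes overlaps of peaks left in place. Both shuffles spread peaks over whole gene spans. Real peaks gather near the cleavage positions, with median midpoints at −163 nt (m6A) and −63 nt (CLIP) from the strongest site. The excess over shuffles therefore cannot tell binding at m6A from a location near the gene end that both kinds of peak share. Restricted to peaks of at least 4-fold enrichment the gene-level odds ratio turned to 0.86 (interval 0.79 to 0.94), with 1.80, 1.47 and 0.72 in the same terciles.

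Photosynthesis genes were bound almost throughout, with CLIP peaks on 25 of 26 members against 42.2% of all genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 6.43e-08). They are abundant transcripts, and in the top tercile of poly(A) level 2250 of 3793 genes had a CLIP peak. m6A stood on 20 of 26 members, with folds of 1.37 to 2.55, so none at 4-fold enrichment. Defence genes had m6A on 1 of 11 members against 72.9% of all genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.000178). SOC1 and RPN10 had both kinds of peak in both replicates, and FYVE1 had m6A only. The other lists did not pass.

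The design links these layers by asking whether genes with m6A and CPSF70 binding shift their site use. Since 11 genes passed, the rule fixed in advance took genes with a change of at least 1 and no overlap between genotypes, 386 of 2001. Both kinds of peak were present in 190 of these (49.2%) and in 48.7% of the others (odds ratio 1.02, interval 0.81 to 1.28, Fisher's exact test p = 0.865). The odds ratio was 0.89 for m6A (Fisher's exact test p = 0.382) and 1.12 for CLIP (p = 0.357). Among the 386, CLIP genes were more often proximal: 204 of 315 proximal genes were bound and 32 of 71 distal ones (odds ratio 2.23, Fisher's exact test p = 0.00288, Benjamini-Hochberg adjusted over 6 tests 0.0173). That odds ratio was 0.80 (interval 0.30 to 2.17), 1.54 (0.64 to 3.77) and 6.93 (1.84 to 29.2) from the bottom to the top tercile of gene level. The intervals overlap, and in the top tercile only 5 distal genes were bound and 8 were not. The same comparison of proximal and distal genes did not pass for both kinds of peak (odds ratio 1.62, Fisher's exact test p = 0.0872, adjusted over 6 tests 0.262). For m6A it went the other way without passing (odds ratio 0.79, Fisher's exact test p = 0.542). Genes with both peaks had a median change of −0.45 and all others −0.35, a difference of −0.10 (interval −0.17 to −0.03), which was 0.00, 0.01 and −0.11 in the terciles. CLIP genes differed from genes without CLIP by −0.20 (interval −0.26 to −0.12), and by −0.02, −0.02 and −0.30 in the terciles. The odds ratio for both kinds of peak fell below 1 with peaks of at least 4-fold enrichment (0.70), without CLIP replicate 1 (0.92) and with overlapping strongest clusters (0.99). With the 11 called genes alone as the shifted genes it was 1.84 (interval 0.47 to 8.60).

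Peaks lay close to the cleavage positions. Of 14818 Col0 sites in genes, 60.2% had an m6A peak of both replicates in the 150 nt upstream, where the far upstream element of the poly(A) signal lies, against 14.7% of random windows in the same genes, and 20.4% had a CLIP peak against 4.73%. Random windows could fall anywhere in the gene span, also far from its end. The m6A peaks had a median length of 357 and 355 nt, longer than the window, so an overlap does not place m6A at that element. m6A midpoints were most frequent 200 to 150 nt upstream of the strongest site of a gene (1976 peaks) and CLIP midpoints in the last 50 nt (1066 peaks). Windows with a CLIP peak held m6A in 81.8% of cases, other windows in 54.6%. Sites that were higher in cpsf70 had m6A upstream in 10 of 70 cases (14.3%) against 61.4% of sites that were not called (Fisher's exact test, Benjamini-Hochberg adjusted p = 2.39e-15), and sites that were lower in 79 of 178 (44.4%, adjusted p = 1.16e-05). Both classes are calls of the fit without rescaling. After rescaling by median ratios limma called 1 site higher and 33 lower, and several of the largest rises were high in cpsf70 replicate 2 alone. These shares therefore describe the called sites and may not hold for sites raised in both libraries. CLIP stood at 7 of 70 higher sites against 22.0% (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0178), and at 23.0% of lower sites, which did not pass. Within 500 nt of the gene end m6A stood at 27.3% of 22 higher sites against 72.0%, and lower sites (64.3%) no longer differed by the test. CLIP there stood at 35.7% of lower sites against 25.7% (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.044) and at 22.7% of higher sites, which did not pass. Over sites with overlapping strongest clusters CLIP at lower sites was 8.42% against 21.9% (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.000925). This is the opposite direction to that within 500 nt of the gene end. Over the same sites m6A at lower sites was 21.1% against 61.0%, and CLIP at higher sites (14.0%) did not pass. With m6A replicate 1 alone m6A at higher sites was 44.3% against 67.3%.

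**Figure D4:**
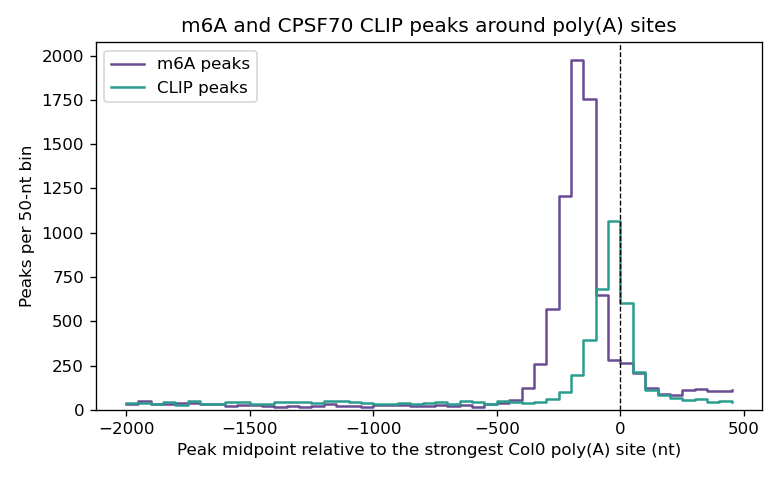
Number of m6A and CLIP peaks of both replicates per 50 nt by the distance of the peak midpoint from the strongest Col0 poly(A) site of the gene (nt, negative upstream). The fullest m6A bin holds 1976 peaks and the fullest CLIP bin 1066.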

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

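No test was run on the values of this part, and no biological explanation was tested. They come from the organelle genomes, which the comparisons of poly(A) sites and of peaks leave out. CLIP peaks lay on the plastid genome in both FLAG-CPSF70 replicates (202 and 155) and on the mitochondrial genome (101 and 81). m6A peaks lay on the plastid genome in both Col0 replicates (31 and 9) and on the mitochondrial genome in replicate 1 (6). Poly(A) clusters lay on the mitochondrial genome in Col0 replicates 1 and 2 (144 and 107).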

How the results depend on the processing

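Joining by gaps, the rule behind the counts in the results, was taken up again after the calls with midpoints had been seen (550 of site use, against 11 by gaps). Joining where bounds touch, robust eBayes, the limit to overlapping strongest clusters, the 3 TPM floor for cpsf70 replicate 1, leaving out peak replicates, sites within 500 nt of the gene end, splits by level other than the top tercile for m6A and CLIP on the same genes, 4-fold enrichment within terciles and all limma alternatives for the authors' deposited table were tests chosen only after the results had been seen. Midpoint joining was set after the files had been looked at, and the others were planned. Counts are of calls. Site abundance had 665 with a variance trend, 5538 with absent values at 0 (3106 higher, 2432 lower), 34 after rescaling, 459 with midpoints (274 higher, 185 lower), 572 with robust eBayes (275 higher, 297 lower), 170 with overlapping strongest clusters and 179 to 332 without a library. Site use had 2 at a mean of 10 TPM, 27 with a trend, 1188 with absent values at 0, 550 with midpoints, 38 where bounds touch, 30 with robust eBayes, 0 with overlapping strongest clusters (309 at an unadjusted p under 0.05 in limma), 72 by diffSplice and 0 to 42 without a library. Gene totals had 280 with a trend, 1670 with absent values at 0, 46 after rescaling, 100 where bounds touch, 101 with overlapping strongest clusters and 114 without cpsf70 replicate 1, the lowest, to 165 without Col0 replicate 1, the highest. With 2 pairs the correlations of deviations (0.198, 0.0872 and 0.250) cannot show whether the replicate numbers pair the libraries, which by the labels share only a number. The replicate block gave 0 calls of site abundance (2207 at an unadjusted p under 0.05 in limma), 80 of site use (17 distal, 63 proximal) and 1 of gene totals, where neither ABI2 nor PR1 passed. The median change of site use was −0.56 at 10 TPM, −0.85 with absent values at 0 and −0.56 to −0.23 without a library. Sites of one genotype numbered 368 in Col0 and 167 in cpsf70 at 10 TPM, 5062 and 7947 with midpoints, and 1738 in cpsf70 at the 3 TPM floor.

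With peaks of at least 4-fold enrichment, shared m6A peaks were 98.2% and 73.1% and shared CLIP peaks 54.2% and 53.3%, the odds ratio of m6A and CLIP on the same genes was 0.86 (0.72 in the top tercile), that of site use 0.70 for both peaks and 0.78 for m6A (Fisher's exact test p = 0.0477), and windows with m6A were 32.7% and with CLIP 12.8%. Windows had CLIP in 18.5% at 100 nt, and m6A in 58.6% and CLIP in 12.4% at an overlap of 50 nt. A single replicate gave 62.0% to 65.8% for m6A and 28.3% to 29.3% for CLIP. For site use the odds ratio of both peaks was 0.99 with overlapping strongest clusters and 0.92 to 1.2 without a peak replicate, that of m6A 1.32 with a peak of either replicate and 0.88 to 1.31 without a replicate, and that of CLIP 0.99 to 1.23 without a replicate. With the 11 called genes alone the odds ratios were 1.84 for both peaks, 0.79 for m6A and 3.15 for CLIP. At lower sites the odds ratio of CLIP was 0.33 with overlapping strongest clusters. A log2 limit of 1 left 27 higher and 16 lower genes of the authors' deposited table.

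Named values that changed sign were PMEPCRA (3.27 with absent values at 0), MBF1B (−0.29 at 50 nt), HOG1 (0.40), APK (−0.10) and emb2726 (−0.038) with midpoints and where bounds touch, and RR1 (−0.94 to 7.74 without a library). Gene totals that had not passed changed sign in FYVE1 (−0.049 with midpoints, −0.077 to 0.55 without a library), PHT1;4 (−0.27 to 0.019 without a library), PHT1;1 (−0.020 to 0.39 without a library), FIP37 (0.33 with midpoints) and RPN10 (0.012 with absent values at 0, −0.47 to 0.15 without a library). All 120 values of the 20 named genes in the authors' deposited table kept direction and call. Of 293 values of 20 named gene totals 266 did, of 120 values of 10 named sites 85, and of 192 values of 16 genes named for site use 127. PR1 had an adjusted p of 0.0475 in limma and did not pass with overlapping strongest clusters. For site use the limit to overlapping strongest clusters removes the called pairs of sites by construction, though a gene such as HOG1 can stay with another pair. For the other alternatives, except as given for joining, the cause was not tested. A test on whole reads, a limit to 3 prime UTRs and motifs around summits were not run, other splits of 2 against 2 libraries cannot reach a share under 0.05, and replicate sharing of peaks has no value without a replicate. Depth limits the low sites: a site at the 3 TPM floor holds few reads in Col0 replicate 2, where 1 read is 0.308 TPM.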

Other observations

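The phosphate list, the test of overlapping strongest clusters, the comparison of libraries of like depth and the count of midpoint calls in different sites were chosen only after the result had been seen, as were the conditions by level named for the targets and by distance named for the joining.

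The phosphate list was drawn up from the authors' deposited table, so its count there is no test: 9 of 25 genes were listed, all higher in cpsf70, namely the transporters PHT1;2 and PHT1;4, the noncoding IPS2, the acid phosphatases PAP14 and PAP17, and SPX3, GDPD1, PS2 and MGD3. In the poly(A) totals 14 of 20 measured members were positive, with a median of 0.24, IPS1 at 0.81, IPS2 at 0.73 and PHT1;4 at −0.12, and none passed. In site use all 4 measured members lay toward the proximal site, with a median of −0.37. Only SQD2 (−1.23) passed, and only when adjusted over the list alone.

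In 4 of 168 genes of the authors' deposited table the genotypes overlapped, and in all 4 the replicates crossed. AT5G09620 stood at 33.6 and 0.568 FPKM in the Col0 libraries and at 0.721 and 36.4 in the cpsf70 libraries of the authors' deposited table, and AT1G12310, AT3G60960 and, less far apart, AT1G01830 had the same form. The folds listed for AT1G12310 (2.68) and AT5G09620 (0.485) in the authors' deposited table go against the means of these FPKM.

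Strong clusters were looked up in the other tables. Of 1491 Col0 clusters with at least 50 TPM in both Col0 tables, 72 (4.83%) had no overlapping cluster in either cpsf70 table, 5 were listed more than 16-fold lower and 15 were 4-fold to 16-fold lower. In the other direction 3 of 1584 lacked a counterpart. The look-up between the Col0 replicates needed 50 TPM in 1 table only, so its shares are no like baseline. There 55 of 2080 clusters of replicate 1 (2.64%) lacked a counterpart and 19 and 23 were listed over 16-fold and 4-fold to 16-fold lower. For replicate 2 these were 98 of 1757 (5.58%), 34 and 55.

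For the genes called toward the proximal site, all 11 had a strongest cluster without an overlapping counterpart, but a missing cluster makes the change and the missing overlap together, so the test is void. Whether these clusters lack a counterpart in the tables as used here because cleavage differed or for a reason of processing cannot be told apart, as no read data were used here. In emb1138 the distal site was not lost: it went from a mean of 93.1 TPM in Col0 to 50.3 TPM in cpsf70, while the proximal site rose from 3.29 to 17.4 TPM. For the wider tendency to the proximal site, the floor and bounds of the tables would need genes whose weaker site is distal to move above 0. Their median was −0.0994 (interval −0.205 to −0.024), with the bound of −0.1 set against this explanation just missed. Genes whose weaker site is proximal had a median of −0.48. Depth would need the deeper library of each genotype to be lower by at least 0.156, and the gap was 0.0427 the other way in Col0 and −0.302 in cpsf70, so Col0 goes against depth. Between libraries of like depth cpsf70 was lower by 0.485 (deeper pair) and 0.140 (shallower pair), the latter within the spread of 0.153 between replicates, and with 2 libraries per genotype a part of depth stays open. Loss of CPSF70 at transcripts with m6A and CLIP peaks met the bound set in advance, with a difference of medians of −0.1029 (interval −0.17 to −0.03), but the difference was 0.00 and 0.01 in the lower terciles of level and 0.06 for m6A alone. CLIP genes differed from the others by −0.20, and by −0.30 (interval −0.40 to −0.18) in the top tercile but −0.02 in each lower one, and genes with CLIP only lay −0.25 from genes with neither peak. A part of CPSF70 binding without m6A therefore stays open, and it and abundance cannot be told apart, as level was not matched within a tercile.

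For the phosphate genes, a phosphate response in cpsf70 seedlings may underlie the rise, and the separate poly(A) libraries did not decide it, with a camera p of 0.6609 at an estimated correlation (preset p 0.0682). More root tissue in the cpsf70 samples stays open too: the root list had a median of 0.031, but only 2 of its members were measured and both belong to the phosphate list, so the test is void.

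For the larger number of calls with midpoints, bounds drawn differently in the tables of the 2 genotypes could split 1 site into 2. The bound set in advance was met: 74.5455% of the 550 called genes had both sites inside 1 gap-joined site, against 54.4% of the uncalled genes (odds ratio 2.46, Fisher's exact test p = 4.9e-19). Real changes between close sites, here a median of 63 nt apart, would give the same value, so these cannot be told apart. In 140 calls the sites lay in different gap-joined sites (91 proximal, 49 distal), more than the 11 calls of joining by gaps. The 2 counts come from different pairs of sites, over 3313 and 2001 genes. A site of such a pair can itself be a part of a split site, so the count cannot place these calls outside the explanation.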
